A study of Mus musculus with 4 samples.

How the data were processed

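Thioglycollate-elicited peritoneal macrophages of 2 Pparg WT and 2 Pparg KO samples were measured, each on 1 Affymetrix array, and genotype and replicate number were taken from the sample titles. Per the labels' protocols, the mice were given 2.5 ml of thioglycollate at 3% and lavaged 3 days later, cells were plated with 10% serum, washed after 5 h and kept for 24 h in 0.5% serum, and labelled cRNA was made from 10 µg of total RNA.

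The deposited table holds 1 intensity value per probe set and array on a linear scale, as the values show; how the authors summarised probes, subtracted background and scaled arrays is not given in the sources used here. Of its 12488 rows, 1780 were blank on all 4 arrays and were not analysed here. After 59 control rows were set aside, 10649 probe sets had values. The platform annotation gave 1 gene for 9389 of these, several for 341 and none for 919, and only probe sets with 1 gene were named. Of the 9389, 9377 matched the gene name table of the GRCm38.p6 assembly by gene identifier, and 0 symbols needed an update. No genome build is named for the arrays, so no coordinates are given and the table served for names and gene neighbourhood only.

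Array medians on the log2(intensity + 16) scale were 7.30 and 7.28 for WT and 7.27 and 7.25 for KO. They differed by less than 0.1, and by the rule set before the data were examined the values were used as deposited. Probe sets with a mean above the 40th percentile (a signal of about 111) were kept, which left 6389. KO was compared with WT by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with a Benjamini-Hochberg adjusted p under 0.05. The estimated prior degrees of freedom were infinite, so each probe set took its spread from the trend over all probe sets at its signal (12778 degrees of freedom in all). Very small p-values rest on that assumption, and a gene more variable than others of its brightness is called too readily. A fit without moderation, and a window of 100 annotated genes on either side of Pparg whether measured or not, were added after seeing the data. Pparg, below the filter, was taken from the fit without it. A gene was represented by its brightest kept probe set, and 5002 genes were tested.

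Before the data were examined, 33 gene lists were fixed from general knowledge, covering lipid metabolism, inflammation and macrophage activation, other cell functions, and markers of macrophages and of other cells a lavage can hold. Of 955 entries, 951 matched a gene. The 30 lists with 5 or more tested members were tested with camera (correlation preset to 0.01) and, beside it, with an estimated correlation and with fry. With 4 arrays, the estimated correlation and the directional fry test rest on 2 residual degrees of freedom. After adjustment over 30 lists they pass only for very large shifts. Mast cell and basophil (4 tested members), eosinophil (1) and adipocyte markers (4) were too few. Genes are named by a rule set before the data were examined: Pparg, the 12 genes per direction with the largest change among those past the threshold whose arrays do not overlap between genotypes, and per list the 4 members with the smallest p or all members that passed where these are up to 4. Other members named as examples were chosen after their values were seen.

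The code was tested on simulated data: for the comparison of 2 arrays with 2, 200 of 6389 probe sets were changed by known amounts. It recovered 100% of those changed by 1 on the log2 scale and 79% of those changed by 0.5, with 7 false calls among 186 and a mean error of 0.02; it called 0 probe sets when nothing was changed, and found the 1 list that was shifted. The simulation used the same pooled spread as the fit and so does not test that assumption.

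Alternatives fixed before the data were examined were quantile normalization, median centring, no filter or the 60th percentile, pseudocounts of 1 and 64, eBayes without trend or robust, an adjusted p of 0.1, an added 1.5-fold rule, the replicate number as a block, each array left out, the mean of a gene's probe sets, and the nearest 50 or 200 tested genes on either side of Pparg, of which 200 takes in all 258 tested on the chromosome. When an array is left out, 1 genotype has a single array, which is assumed to vary like the other genotype. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.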

Results

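RNA was measured in macrophages labelled as wild type for the Pparg gene (WT) and in macrophages labelled as Pparg knockouts (KO). Pparg encodes the lipid-activated nuclear receptor PPARγ. The cells were peritoneal macrophages recruited by thioglycollate, an irritant that draws monocyte-derived cells into the peritoneal cavity, and they received no ligand or stimulus in culture. Each genotype had 2 arrays, 4 in all, on a 1-colour Affymetrix platform. The median signal of the arrays ran from 137 to 142 intensity units, and between 75.2% and 82.3% of tested probe sets exceeded the highest antisense control of an array. The labels do not say whether the 2 arrays of a genotype came from separate mice or cultures, and the description of replicate 2 of each genotype carries the suffix dup, so p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision. Values below are mean signals ± SD (n = 2), log2 fold changes are KO minus WT on the log2(signal + 16) scale, and adjusted p-values are limma's with Benjamini-Hochberg adjustment. Every fold is taken on the same scale, after adding 16 to each signal, so it can differ from the ratio of the mean signals printed beside it and understates changes of dim probe sets.

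The targeted gene was measured first. The 1 Pparg probe set with values read 61.1 and 73.1 on the WT arrays and 43.0 and 40.6 on the KO arrays, a log2 fold change of -0.52 (SE 0.11, adjusted p = 0.00012 in the fit without a signal filter). These signals were dim, all 4 below the antisense control median of their array, so no fold is given and the size of the log2 difference depends on the pseudocount: it was -0.66 with a pseudocount of 1 and -0.31 with 64, past the threshold in both. The probe set ranked at the 12.5th percentile of all probe sets, and its KO mean of 41.8 lay between the median yeast control (25.6) and the median antisense control (109.0) of the KO arrays. The deleted part of the gene is not described in the labels, so the probe set may lie outside it and then checks nothing. Without WT replicate 2 the log2 fold change was -0.42 and adjusted p = 0.14. It did not meet a 1.5-fold rule with the pseudocount of 16, and without variance moderation adjusted p = 0.74.

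The comparison of KO with WT asked which transcripts differ when Pparg is missing in otherwise untreated macrophages. Of 6389 probe sets tested, 227 passed an adjusted p of 0.05, 65 of them higher and 162 lower in KO. By gene, 53 were higher and 133 lower among 5002 genes. Falls were also larger than rises: 22 of the called probe sets were lower by 2-fold or more and 1 was higher by as much. The KO arrays lay wholly above or below the WT arrays at 32.4% of tested probe sets, where chance gives 33.3%. Quantile normalization called 419 probe sets, 170 higher (40.6%) and 249 lower, against 28.6% higher with the values as deposited.

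The counts depended on single arrays and on how the spread was estimated. When a WT array was left out, the spread came from the KO pair alone. The KO arrays differed more (SD of their difference 0.17 over tested probe sets) than the WT arrays did (0.14). Their difference also shifted with brightness. In the brightest decile of tested probe sets, KO replicate 2 exceeded KO replicate 1 by a median of 0.21 on the log2 scale. WT replicate 2 exceeded WT replicate 1 by 0.07 there. In the dimmest decile these medians were -0.009 for KO and -0.03 for WT. The rule on array medians does not detect such a shift. A call lost without a WT array therefore need not mean a smaller effect. The median log2 fold change of the interferon list was -0.56 without WT replicate 1 and -0.62 without WT replicate 2, against -0.58. Without WT replicate 1 there were 72 calls (19 higher, 53 lower), and without WT replicate 2 there were 56 (8 higher, 48 lower). Leaving out KO replicate 1 gave 129 higher and 126 lower, and leaving out KO replicate 2 gave 41 higher and 288 lower. With each probe set's own 2 residual degrees of freedom and no moderation, limma called 0 probe sets, and 388 had an unadjusted p under 0.05, against 605 with moderation. Chance alone puts a share of 0.05 of the 6389 tested probe sets under that p, so many of the 388 can be chance.

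GTPase genes of innate immunity were among the largest falls. Iigp1, an immunity-related GTPase, fell from 2275 ± 66.6 to 387.5 ± 19.7, a fold of 5.68 on the scale of the fit (log2 fold change -2.51, SE 0.16, adjusted p = 2.17e-54), and its other probe set gave -2.42. Cst7, which encodes the cysteine protease inhibitor cystatin F, fell 3.32-fold from 407 to 112. The guanylate-binding protein genes Gbp3, Gbp2 and Gbp7 fell 2.26-fold, 2.20-fold and 2.20-fold. Fpr2, a formyl peptide receptor, fell 2.58-fold, and Socs1, a feedback inhibitor of cytokine signalling, fell 2.31-fold. The other genes of this set were Snhg6 (at least 1.99-fold), AW112010 (2.45-fold), Ralgds (2.39-fold), Ifit2 (2.15-fold) and the class I-like gene H2-M2 (2.15-fold). Both KO signals of Snhg6 (mean 75.5, adjusted p = 6.69e-36) lay below the antisense control median of their array, which then stands in for them, so its fold is a lower bound. The dimmer probe set of Ralgds did not follow (log2 fold change -0.11). When each array was left out in turn, 11 of these 12 genes stayed past the threshold, and Gbp2 missed it without WT replicate 1 (log2 fold change -1.08, adjusted p = 0.073).

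The largest rises were smaller. Cdkn1c, which encodes the cyclin-dependent kinase inhibitor p57, rose 1.95-fold from 170 ± 3.61 to 348 ± 38.8 (log2 fold change 0.97, SE 0.12, adjusted p = 9.82e-14). Mrc1, the macrophage mannose receptor, read 93.9 in WT, below the antisense control median of both arrays, and 190 in KO (adjusted p = 1.04e-13), which is at least 1.63-fold higher against that median. Arg1, arginase 1, rose 1.84-fold from 232 to 439. Cd24a (1.75-fold), Emp1 (1.71-fold), the proteoglycan decorin gene Dcn (1.68-fold), the macrophage elastase gene Mmp12 (1.66-fold) and Igf1 (1.63-fold) followed. The remaining genes were Dio2, which encodes the deiodinase that activates thyroid hormone (1.60-fold), the complement receptor gene C3ar1 (1.59-fold), Cd5l (1.59-fold) and Gas1 (1.56-fold). A second Igf1 probe set read 0.36 on the log2 scale with adjusted p = 0.25. Of these 12 genes, 7 stayed past the threshold without WT replicate 1 and 3 (Cdkn1c, Mrc1 and Dio2) without WT replicate 2. Emp1, Dcn, Mmp12, Igf1 and C3ar1 missed it without either WT array, at adjusted p from 0.14 to 0.9999, and Arg1, Cd24a, Cd5l and Gas1 without WT replicate 2, at adjusted p from 0.067 to 0.11.

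**Figure D1:**
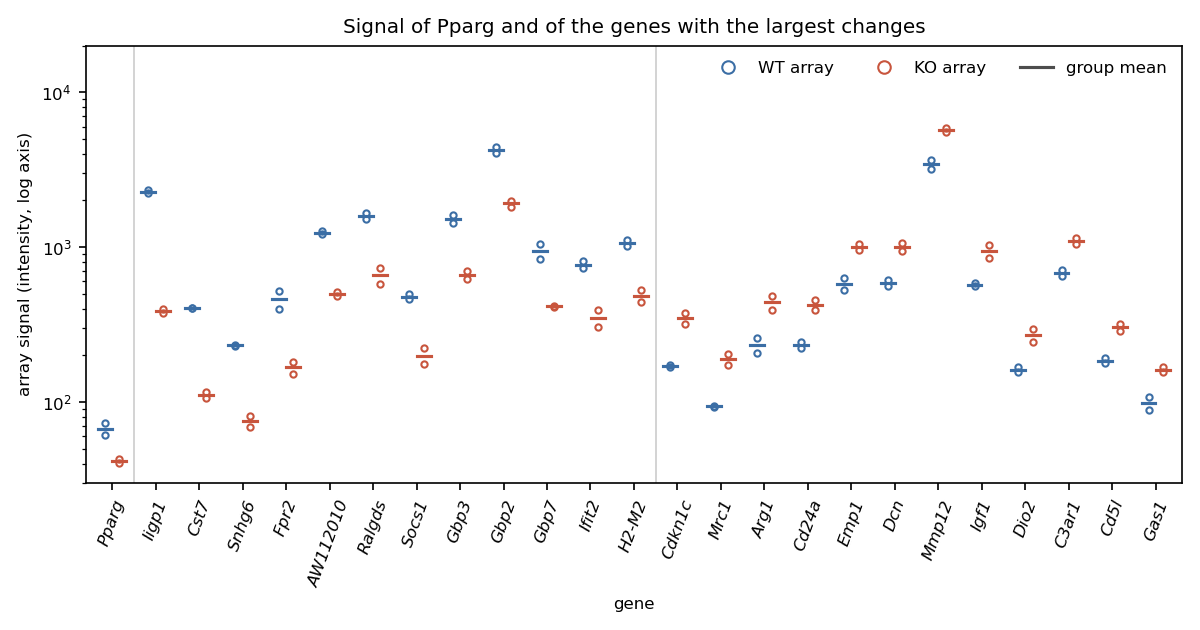
Array signal (intensity, logarithmic axis) of Pparg and of the 24 genes with the largest falls and rises past the threshold, with open circles for single arrays (blue WT, red KO) and bars for group means. Both KO arrays lie beyond both WT arrays for every gene drawn, as the choice of the 24 genes required. Examples are the fall of Iigp1 (2275 to 387.5) and the rise of Mmp12 (3422 to 5680).

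Genes induced by interferons fell together. Of 29 members tested, 20 fell, 0 rose and 9 did not pass (27 fell when adjusted over the list alone), with a median log2 fold change of -0.58. Besides Iigp1, Gbp3 and Ifit2, Ifit1 fell from 236 ± 9.19 to 119 ± 14.1 (log2 fold change -0.90, SE 0.11, adjusted p = 1.04e-13). Irf9, a subunit of the factor that carries type I interferon signals, read 415.6 in WT and 419 in KO and did not pass. The list passed camera (adjusted p = 1.85e-56), a test of a list against the other genes with a preset correlation, and not with an estimated correlation (adjusted p = 0.44). The second test rests on 2 residual degrees of freedom and can hardly pass after adjustment, here and for the lists below. Missing it therefore decides little. The number of fallen members was 7 without WT replicate 1, 7 without WT replicate 2, 17 without KO replicate 1 and 27 without KO replicate 2.

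Genes of antigen presentation on MHC class II fell as well. Of 10 members, 7 fell, 0 rose and 3 did not pass, over all genes and when adjusted over the list alone, with a median log2 fold change of -0.77. H2-DMa, which helps load peptides, fell 1.97-fold from 3085 ± 143 to 1563 ± 121 (log2 fold change -0.98, SE 0.16, adjusted p = 9.94e-08). The chains H2-Aa, H2-Ab1 and H2-Eb1 fell by 1.89-fold, 1.88-fold and 1.87-fold. The other members that fell were H2-DMb1, the invariant chain gene Cd74 and the class II transactivator gene Ciita. Ctss, the protease that trims the invariant chain, read 9250 in WT and 9469 in KO and did not pass. The list passed camera at adjusted p = 2.26e-15 and missed it with an estimated correlation (adjusted p = 0.44). Without WT replicate 1 the number of fallen members was 1 and without WT replicate 2 it was 0, with medians of -0.86 and -0.68; the 4 H2 genes named with folds then had adjusted p from 0.058 to 0.42. H2-DMb1 and Cd74 missed the threshold without either WT array (adjusted p from 0.17 to 0.80) and Ciita without WT replicate 2 (0.11). Markers of dendritic cells (median log2 fold change -0.08, 0 of 5 past the threshold), B cells (0.08, or -0.03 without a filter) and T and NK cells (0.01, or -0.07 without a filter) are given beside this group because such cells also carry class II or interferon-induced transcripts.

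Inflammatory genes on the NF-kB list were lower in part. Of 27 members, 9 fell, 1 rose and 17 did not pass (12 fell and 2 rose when adjusted over the list alone), with a median log2 fold change of -0.23. Whether these falls are separate from those of the interferon genes was not tested, and Cxcl10 was fixed as a member of both lists. After quantile normalization 3 rose. Ptges, which makes prostaglandin E synthase, fell 1.94-fold from 356 ± 21.3 to 176 ± 12.8 (log2 fold change -0.96, SE 0.12, adjusted p = 2.51e-13). The adhesion molecule gene Icam1 fell 1.89-fold, the lectin gene Clec4e 1.73-fold and the costimulatory gene Cd86 1.48-fold. The chemokine genes Ccl2 (1475 in WT, 1372 in KO) and Ccl3 (614 and 691) did not pass, and Cxcl1 rose from 165 to 218. Camera gave adjusted p = 1.48e-08, and adjusted p = 0.68 with an estimated correlation. The fallen members numbered 4 without WT replicate 1, 3 without WT replicate 2 and 5 without KO replicate 1, and Cd86 missed the threshold without either WT array (adjusted p = 0.076 and 0.14). Cxcl1 missed it without WT replicate 1 (0.90), WT replicate 2 (0.76) or KO replicate 2 (0.16), without a filter (0.059) and with the mean of its probe sets (0.060).

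Some genes of alternative activation, the state induced by interleukin-4, moved up and 1 moved down. Of 16 members, 4 rose (Mrc1, whose WT signal lay below the antisense control median, Arg1, Mmp12 and Igf1), 1 fell (Socs1) and 11 did not pass, over all genes and when adjusted over the list alone. The median log2 fold change was 0.12, and without a filter it turned to -0.02 over 22 members, with camera adjusted p = 0.044 and the test still pointing up. Chil3, a chitinase-like gene typical of the state, read 165.5 in WT and 193 in KO and did not pass, and Mmp12 and Igf1 are also made by other macrophage states. The list had camera adjusted p = 0.0044, or 0.055 without WT replicate 2 and adjusted p = 0.73 with an estimated correlation. Without WT replicate 1, 2 members rose, and without WT replicate 2, 1 did.

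Matrix and protease genes went both ways. Of 15 members, 4 rose, 1 fell and 10 did not pass (6 rose and 2 fell when adjusted over the list alone), with a median log2 fold change of 0.17. The median was 0.16 without WT replicate 1, 0.22 without WT replicate 2, 0.32 without KO replicate 1 and 0.05 without KO replicate 2. After quantile normalization 8 rose and 2 fell. Sparc, a secreted matrix glycoprotein, rose from 97.5, below the antisense control median of both WT arrays, to 160, at least 1.39-fold against that median. The metalloprotease genes Mmp12 and Mmp8 rose 1.66-fold and 1.49-fold, and Adam8 rose 1.54-fold, while Tgfbi fell 1.42-fold from 390 to 269. Camera gave adjusted p = 0.00012, and adjusted p = 0.68 with an estimated correlation. The members that rose numbered 2 without WT replicate 1, 1 without WT replicate 2 and 7 without KO replicate 1; Adam8 (adjusted p = 0.9997 and 0.76) and Tgfbi (0.9997 and 0.16) missed the threshold without either WT array, and Mmp8 without WT replicate 2 (adjusted p = 0.46). Of 14 fibroblast and mesothelial markers, 1 rose (Dcn) and 13 did not pass, 6 rose when adjusted over the list alone, and 13 were higher in KO, with a median of 0.20. Col1a2 read 329 in WT and 430 in KO (adjusted p = 0.12), and Col6a1 read 219 and 279 (adjusted p = 0.11). The markers had camera adjusted p = 1.79e-06, and adjusted p = 0.44 with an estimated correlation. Without either WT array 0 of these markers rose, and without KO replicate 1, 5 did. Quantile normalization called 4 of them, the fit without the trend 2, and the fit without a filter 3 of 25.

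Cholesterol synthesis genes were higher in KO. All 12 members tested had higher means in KO, 4 of them past the threshold and 6 when adjusted over the list alone, and the median log2 fold change was 0.29. Idi1, which makes isopentenyl diphosphate isomerase, rose 1.47-fold from 273 ± 22.4 to 410 ± 53.6 (log2 fold change 0.56, SE 0.13, adjusted p = 0.00093). Sqle, squalene epoxidase, rose 1.46-fold, Msmo1 1.40-fold and Cyp51 1.35-fold. Camera gave adjusted p = 1.48e-08, and adjusted p = 0.61 with an estimated correlation. Quantile normalization called 7 members. Without either WT array 0 members passed, the 4 named genes then having adjusted p from 0.15 to 0.9999, and Sqle also missed the threshold without KO replicate 2 (0.052).

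Lipid genes that respond to PPAR receptors did not pass as a group, though 12 of 17 had lower means in KO and 5 higher. Of 17 members, 1 rose, 0 fell and 16 did not pass (1 rose and 3 fell when adjusted over the list alone), with a median log2 fold change of -0.07 and camera adjusted p = 0.46. The median was -0.14 without WT replicate 1, -0.08 without WT replicate 2, -0.05 without KO replicate 1 and -0.15 without KO replicate 2. The riser was Fabp4, a fatty acid binding protein gene, from a dim 122 to 159.5 (log2 fold change 0.35, SE 0.11, adjusted p = 0.042). It missed the threshold without WT replicate 1 (0.14), WT replicate 2 (0.9999) or KO replicate 2 (0.40), without a filter (0.069), without the trend (0.058) and with robust moderation (0.0504). Nr1h3, which encodes the liver X receptor LXRα, read 305 in WT and 232 in KO (log2 fold change -0.37, adjusted p = 0.061), Pex11a read 195 and 154 (adjusted p = 0.11) and Lipe 198 and 159 (adjusted p = 0.18). Fatty acid oxidation genes had 0 of 17 members past the threshold (camera adjusted p = 0.86), with Cpt1a at 801 and 648 (adjusted p = 0.50). Targets of LXR and lipogenic genes had 0 of 15 (1 fell when adjusted over the list alone; camera adjusted p = 0.56), with Apoe at 4477 and 5815 (adjusted p = 0.21). After quantile normalization 1 PPAR-responsive gene fell, and 2 genes of the LXR list rose and 1 fell. With the replicate number as a block, 4 PPAR-responsive genes fell and 1 rose (camera adjusted p = 0.42). In that fit 1 gene of the LXR list rose and 1 fell, and 1 fatty acid oxidation gene fell.

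**Figure D2:**
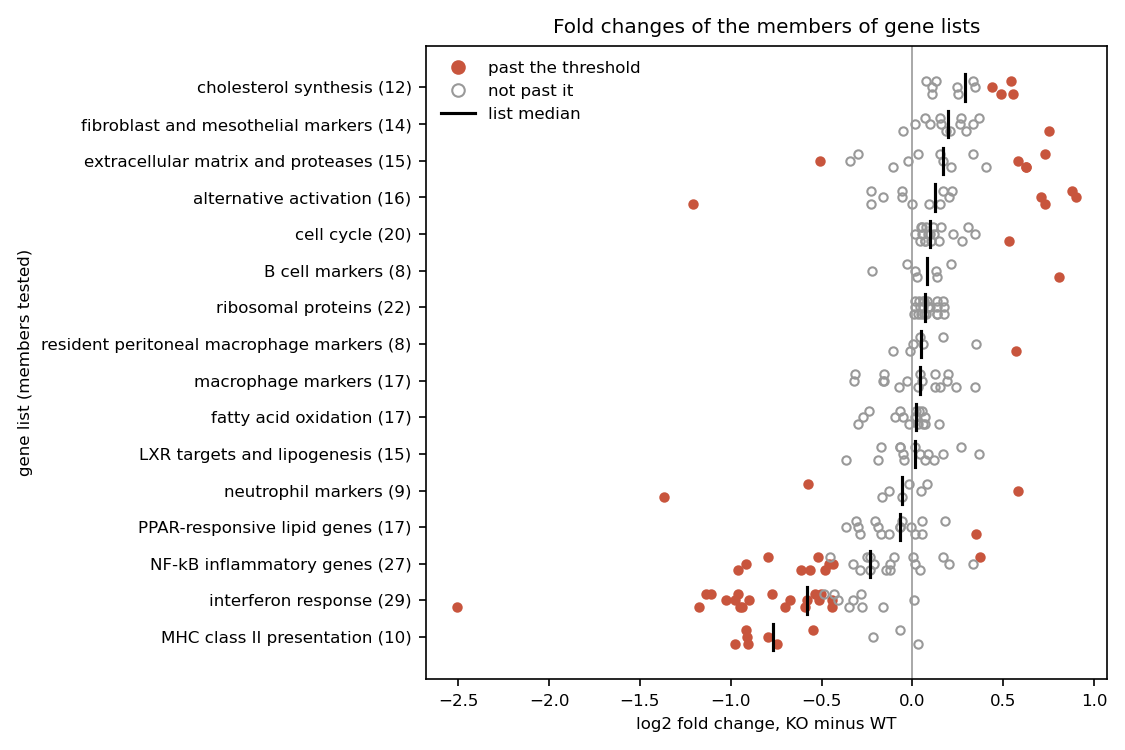
Log2 fold change, KO minus WT, of each tested member (points, filled red where past the threshold) of the 12 gene lists that passed camera and of 4 lists on lipids and macrophage identity, with black bars for list medians. MHC class II and interferon genes lie furthest to the left, with medians of -0.77 and -0.58, and cholesterol synthesis genes furthest to the right, with a median of 0.29.

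Cell cycle genes had slightly higher means in KO. All 20 members had higher means in KO, 1 of them past the threshold and 3 when adjusted over the list alone, with a median log2 fold change of 0.10. Mcm3, a subunit of the replication helicase, rose from 221 to 326 (log2 fold change 0.53, adjusted p = 0.00066), while Stmn1 (112 and 147, adjusted p = 0.051) and Cdk1 (125 and 158, adjusted p = 0.12) did not pass. For the list, camera gave adjusted p = 2.38e-05, an estimated correlation adjusted p = 0.44, and fry adjusted p = 0.13 for a shift in one direction and adjusted p = 0.00045 for change in either direction. Quantile normalization called 2 members. Mcm3 missed the threshold without WT replicate 1 (0.28) or WT replicate 2 (0.47).

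Markers of macrophages did not separate the genotypes, with 0 of 17 past the threshold, a median log2 fold change of 0.04 and camera adjusted p = 0.53. Adgre1, which encodes F4/80, read 1425 in WT and 1138 in KO (adjusted p = 0.46). Of 8 markers of resident peritoneal macrophages, Cxcl13, a B cell attracting chemokine gene, rose from 233 to 354 (adjusted p = 0.00026). It missed the threshold without WT replicate 1 (0.069) or 2 (0.85). The list had camera adjusted p = 0.038, or 0.098 without WT replicate 2 and 0.26 without KO replicate 2, and adjusted p = 0.94 with an estimated correlation. Of 9 neutrophil markers, Fpr2 and the calprotectin subunit gene S100a8 (530 to 350.5) fell and Mmp8 rose, with camera adjusted p = 0.041, or 0.25 without WT replicate 1, 0.37 without KO replicate 2 and 0.23 after quantile normalization, and adjusted p = 0.61 with an estimated correlation. S100a8 missed the threshold without WT replicate 1 (0.41) or 2 (0.74), and macrophages also express all 3 of these genes. Of 8 B cell markers, Cd24a, which is not specific to B cells, rose, with camera adjusted p = 0.028, or 0.14 without WT replicate 1 and 0.054 without KO replicate 1, and adjusted p = 0.61 with an estimated correlation. Cd24a missed the threshold without WT replicate 2 (0.067). Ribosomal protein genes had 0 of 22 members past the threshold, a median of 0.07 and camera adjusted p = 0.028, or 0.52 without WT replicate 1 and 0.34 without KO replicate 2, and adjusted p = 0.95 with an estimated correlation. These 4 lists gave the same counts when adjusted over the list alone. Without a filter on dim probe sets none of these 4 passed camera (adjusted p from 0.10 to 0.32), and the B cell median turned to -0.03. Without KO replicate 2 the medians of ribosomal protein genes and resident macrophage markers turned to -0.01 and -0.03. Quantile normalization called 2 resident macrophage and 2 B cell markers as higher.

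The other lists did not pass camera. For phagocytosis and the clearance of dying cells (adjusted p = 0.080), C3ar1 and C5ar1 rose and Mertk, a receptor for dying cells, fell from 229.5 to 143 (adjusted p = 1.37e-06) among 26 members; its median was -0.01 while its mean was 0.06 and the test pointed up. After quantile normalization 6 phagocytosis members rose and the median was 0.03, and without KO replicate 1, 6 rose and it was 0.08. Sod2, the mitochondrial superoxide dismutase gene, fell from 824 to 443 (adjusted p = 3.31e-07) and Gclm from 399 to 275 among 25 genes of oxidative stress (camera adjusted p = 0.67). Hif1a, the hypoxia-inducible factor gene, fell from 1768 to 1202 (adjusted p = 0.018) among 21 genes of glycolysis and hypoxia (0.67), with a second probe set at -0.43 on the log2 scale (adjusted p = 0.13). Single members also passed among 12 heat shock genes (the collagen chaperone gene Serpinh1 rose; 0.55), 12 nuclear receptors and coregulators (Med1 fell; 0.56), 38 lysosomal genes (Gla fell; 0.56), 23 chemokine and cytokine receptors (Cxcr4 rose; 0.98) and 10 T and NK cell markers (Ccl5, also on the NF-kB list and made by macrophages, fell; 0.80). Of the genes in this paragraph, Mertk kept its call whichever array was left out. C3ar1, C5ar1, Sod2, Gclm, Hif1a, Serpinh1, Gla and Ccl5 missed the threshold without either WT array, at adjusted p from 0.058 to 0.9999. Med1 and Cxcr4 missed it without WT replicate 2 (0.051 and 0.9999) and KO replicate 2 (0.22 and 0.059), and Med1 also without WT replicate 1 (0.9997). C5ar1 missed it without KO replicate 2 (0.13) and Gla without KO replicate 1 (0.21) or a filter (0.068), Gla and Hif1a after median centring (0.089 and 0.075) and Med1 after quantile normalization (0.0504). Adjusted over the list alone, 3 phagocytosis genes rose, 1 gene of the unfolded protein response, 2 nuclear receptor or coregulator genes and 2 genes of glycolysis and hypoxia fell, and the counts of the other lists in this paragraph stood as given. Without KO replicate 1, the phagocytosis list (0.0040), lysosomal genes (0.028) and macrophage markers (0.016) passed camera, without the trend the phagocytosis list did (0.043), and after quantile normalization the phagocytosis list (0.019) and the unfolded protein response (0.042) did. None of 42 oxidative phosphorylation, 20 TCA cycle, 19 unfolded protein response, 18 immediate early, 5 dendritic cell or 6 erythroid and platelet genes passed, with camera adjusted p of 0.55, 0.56, 0.11, 0.55, 0.56 and 0.70.

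The mice had a mixed 129/SV and C57BL/6 background, and the last comparison asked whether called genes were concentrated around Pparg. Among the tested genes nearest to Pparg, up to 100 on either side and 183 in all, which is most of the 258 tested on its chromosome, 6 were called, which is 3.28%, against 3.74% of 4819 other genes (odds ratio 0.87, 95% confidence interval 0.31 to 1.98, two-sided Fisher's exact test p = 1). A narrower window of the nearest 100 annotated genes on either side, measured or not, was added after seeing the data and held 20 tested genes, of which limma called 0 and 0 had an unadjusted p under 0.05 (odds ratio 0, 95% confidence interval 0 to 5.27). The 6 genes were C3ar1, Clec4e, Emp1, Itpr2, Ptpn6 and Usp18, named after their values were seen where they lie outside the sets above. Itpr2, Ptpn6 and Usp18, all lower in KO, missed the threshold without WT replicate 1, WT replicate 2 or KO replicate 1 (adjusted p from 0.16 to 0.9999), and Itpr2 and Ptpn6 after median centring (0.089 and 0.11).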

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

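The tests of explanations in this part were chosen after the results were seen, though the quantile normalization and the window around Pparg that they use were planned. A control probe set outside the comparison was higher in KO: the 3' probe set of the transferrin receptor among the array's own controls read 310 and 320 in WT and 405 and 453 in KO, 1.34-fold higher (log2 fold change 0.42, limma's adjusted p = 0.040). The regular probe sets for this gene, Tfrc, gave log2 fold changes of 0.41 (adjusted p = 0.013) and 0.41 (adjusted p = 0.17). The control and the first of these missed the threshold without WT replicate 1 (adjusted p = 0.9997 and 0.67), WT replicate 2 (0.9999 and 0.72) or KO replicate 2 (0.11 and 0.30). Another control probe set, for mouse FAS by its name on the array, was lower in KO (152 and 138 against 90.1 and 101, log2 fold change -0.53, adjusted p = 8.13e-05, or 0.090 without WT replicate 1).

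Interferon and MHC class II genes were lower in KO together, and 27 genes of both lists fell. Array scaling is argued against: after quantile normalization the medians were -0.54 and -0.74. Alleles linked to Pparg that act on nearby genes would not account for most of the 27. Of these, 1 (Usp18) lies among the 183 tested genes flanking Pparg, a window that spans most of the 258 tested on its chromosome. That count follows from where the genes lie and not from their values, and a linked allele of a regulator remains open. Fewer lymphocytes or dendritic cells in the KO cultures cannot be told apart from a change within macrophages: the lowest median of their marker lists was -0.083, but no more than 8 of 23 markers exceeded 2 times the highest antisense control. A lower exposure of the KO cells to interferon, in the mouse or the dish, and unlinked background alleles may also contribute and were not tested, so the effect of genotype stays a hypothesis.

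Lipid genes responsive to PPAR receptors did not pass camera as a group, with 12 of 17 lower in KO, although the Pparg probe set fell. The 8 brighter members had a median log2 fold change of -0.10 (95% resampling interval over genes, -0.19 to 0.06). For these members, this argues against dim probe sets hiding a change as low as the fitted -0.52 of Pparg. That value itself comes from signals below the antisense control median. The interval does not cover the spread between arrays, and smaller falls remain open. Incomplete deletion cannot be told apart from loss of the receptor, since the KO signal of 41.8 lies between the control levels and the position of the probe set in the gene is unknown. That a receptor without added ligand may contribute little to these genes is a hypothesis these samples do not test.

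Of 14 fibroblast and mesothelial markers, 13 had higher means in KO and 1 (Dcn) passed the threshold; the list passed camera, but not with an estimated correlation (adjusted p = 0.44) or by fry (adjusted p = 0.25). More fibroblasts or mesothelial cells in the KO cultures may account for this and cannot be told apart from a change within macrophages. After subtraction of the antisense control median, Dcn rose by 0.42 more on the log2 scale than the mean of Col1a1, Col1a2 and Col3a1 (0.90 against 0.48), but the 95% interval of that difference ran from -0.46 to 1.30. The other members had a median of 0.18, too small to decide. An effect of genotype on these genes in macrophages was not tested apart from this.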

How the results depend on the processing

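The fit without moderation and the window of annotated genes around Pparg were chosen after seeing the data; the other settings were planned. No gene or tested list reversed direction while called, but the median of the alternative activation list turned to -0.02 without a filter. The excess of lower over higher calls did not hold without KO replicate 1. Median centring, no filter, the 60th percentile, both pseudocounts, no trend, robust moderation, an adjusted p of 0.1 and, for genes, the mean of probe sets left the counts of probe sets (182 to 331) and genes within 1.5 times of 227, 53 and 133. Quantile normalization gave 419 probe sets (170 higher, 249 lower; 220 shared with the values as deposited), 137 genes higher and 191 lower. The 1.5-fold rule left 90 probe sets (19 higher, 71 lower), 16 genes higher and 57 lower, and Pparg (-0.52) failed it. Without moderation 0 probe sets and 0 genes passed in either direction, and Pparg (-0.52) had adjusted p = 0.74. The cause was not tested, except that the 2 residual degrees of freedom limit the last. Lists past the threshold numbered 8 to 14 under camera, 0 with an estimated correlation and 0 by fry. The last 2 tests rest on 2 residual degrees of freedom, so a list could hardly pass them after adjustment. The robust, fold-rule and unmoderated settings do not enter camera, and Pparg has no value under the 60th percentile filter.

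Leaving out each array in turn gave 56 to 329 probe sets (8 to 129 higher, 48 to 288 lower), 6 to 108 genes higher, 37 to 229 lower, 9 to 14 lists, an odds ratio near Pparg of 0.51 to 0.94 and a Pparg log2 fold change of -0.62 to -0.42, against -0.66 with a pseudocount of 1 and -0.31 with 64. Of 54 called genes named by rule besides Pparg, 20 kept their call in every setting that tested them. The fold rule and no moderation were left out of that count, and a gene below a setting's filter was not tested there. Lost calls came mainly from leaving out a WT array rather than a KO array. Odds ratios near Pparg ran from 0 in the window of annotated genes to 1.48 with the 60th percentile filter, none past the threshold. Without moderation 0 genes were called anywhere, so no odds ratio could be formed.

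With the replicate number as a block, 480 probe sets passed (142 higher, 338 lower; 227 shared), with 115 genes higher and 260 lower. The differences between replicates 1 and 2 correlated at 0.42 across probe sets between the genotypes, but with 2 pairs and no label of a shared day the arrays share only a number. The 2 other splits of the 4 arrays gave 0 calls each, against 227, too few splits for a share under 0.05. In those fits the difference between genotypes counts as spread, which makes calls harder to reach. Signal over background limits dim genes, Pparg among them.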

Other observations

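Further members of the interferon list were lower in KO, while the receptors for interferons did not pass. Of the members not described so far, Igtp fell 2.04-fold from 635 to 304 and the transcription factor genes Irf8 and Irf1 fell 1.97-fold and 1.94-fold, from 2456 to 1244 and from 2611 to 1341. Irf7 fell 1.71-fold and the peptide transporter gene Tap1 1.63-fold, while the immunoproteasome genes Psmb8 (3011 in WT, 2145 in KO, adjusted p = 0.0504), Psmb9 (adjusted p = 0.11) and Psmb10 (adjusted p = 0.43) did not pass. Igtp kept its call whichever array was left out. Irf8, Irf1, Irf7 and Tap1 missed the threshold without WT replicate 1 (adjusted p from 0.080 to 0.79) or WT replicate 2 (0.22 to 0.93). The interferon receptor genes Ifnar1 (363 and 403), Ifnar2 (334 and 271), Ifngr1 (227 and 259) and Ifngr2 (260 and 277) did not pass either. Adjusted p-values are limma's, and these genes were chosen after their values were seen.

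The share of genes called differed between chromosomes, from 1.80% of 111 genes on chromosome 18 to 7.38% of 149 on chromosome 12; on chromosome 17, which holds the H2 genes, it was 6.09% of 312, and on chromosome 6, which holds Pparg, 4.65% of 258. These shares were not tested. A pair of probe sets assigned to Actb read 60.6 and 25.6 in WT, while the array's own actin controls read 6614 to 10765 on the WT arrays. Whether these probe sets match the Actb transcript was not checked.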
